A study of Homo sapiens with 42 samples.

How the data were processed

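The series holds RNA-seq of 7 human cancer cell lines, each with 3 libraries after a non-targeting siRNA and 3 after siRNAs against YAP and TAZ, 42 libraries in 14 groups, 48 h after transfection. Per the labels' protocols, RNA was extracted with an RNeasy kit, libraries were made with a TruSeq RNA v2 kit, which does not mark the strand, and single-end reads were generated on a HiSeq2500. The deposited values are read counts per gene that the authors made, with genes named by Entrez identifiers. Per the submitters' processing notes, GSNAP, DESeq2 and limma were used with the GRCh38 build; the roles and versions of these tools are not given there, and the counting tool and annotation are not given in the sources used here. Values in both tables are whole numbers without any sign of scaling, 1 table holding Detroit 562 (6 libraries) and the other the remaining 6 lines (36 libraries), and 0 columns were left unused. Whether replicates were separate transfections, and the day of each, is not given. Without strand, reads of overlapping and antisense genes cannot be separated, and the handling of reads that match several near-identical genes is unknown.

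Identifiers were matched to symbols in the RefSeq gene table of GRCh38.p14: 27814 of 30727 matched, and the 2913 others, which held 0.37% of all counts, stayed in library sizes and tests under their number and were never named. No mitochondrially encoded gene is in the tables. Total counts ran from 21.2 M to 52.3 M per library, with medians per line from 22.4 M (SF268) to 36.7 M (ES-2). Counts were analysed in R 4.3.3 with edgeR 4.0.16: TMM factors, filterByExpr, robust quasi-likelihood fits (glmQLFit, glmQLFTest) and Benjamini-Hochberg adjustment at 0.05. Each line was fitted alone on its 6 libraries, without covariates, because the labels name no batch, day or pairing. The average over 6 lines and the differences between them came from a single fit of 36 libraries with 12 line-by-treatment groups, which leaves out Detroit 562. Genes with no reads in both groups of a line have no usable error on the average and could not be called there. Genes called in a single direction in all 7 lines were counted and set against the number expected from independent lists.

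The 18 gene lists (382 genes) were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2, two-sided, with a preset correlation of 0.01 and adjustment over the lists of a line. The same test with the correlation estimated from the data is reported beside it, and fry, which asks whether a list's genes move on balance one way or change in either direction without comparing them with other genes, was an alternative. Members of a list were counted by their adjusted p over all genes of the line and also adjusted over the list alone. AMOTL2, LATS2 and PTPN14 are in both the target list and the Hippo list, and SESN2 is in both the p53 and the ER stress list. The comparisons, lists, tests, naming rule and most alternatives were fixed before the data were examined. Added after that were the list tests on the 6-line average, a joint fit limited to genes past the filter in all 6 lines, a minimum spread of 1 between the lines' log2 fold changes, and tests of lists of FOXO and retinoic acid targets. That rule named, per line, YAP1 and WWTR1, the 5 largest rises and 5 largest falls among genes past the threshold with at least 5 CPM in the higher group, a symbol and no overlap between the groups, and up to 4 members of each list with the smallest adjusted p; for the 6-line average the 10 largest rises and falls with at least 5 CPM in the higher group of at least 3 lines and 1 sign in all 6; for the differences between lines the 10 smallest p with at least 5 CPM in the highest group; and for genes called in all 7 lines the 10 with the largest mean absolute change. Members of lists that moved against the rest, or did not pass, and marker genes were named outside this rule, after their values were seen.

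The tests were tried on simulated counts drawn from the means and library sizes of the real libraries, with 200 genes and the target list changed per line; in the joint fit 200 genes changed alike in all 6 lines and 200 others in ES-2 alone. Per line, 88% (OVCAR-8) to 96% (HCC1954 and RVH-421) of 1.5-fold changes and 98% to 100% of 2-fold changes were recovered, and 6 to 15 unchanged genes were called. For the 6-line average (19032 genes) 100% of both sizes were recovered, and for the differences between lines 92% and 100%. A list shifted by -0.5 was found in all 7 lines. Simulated genes were drawn independently of each other, and far fewer were changed than the 12.6% to 72.3% called in the real lines. These rates do not cover correlated genes. The list result does not show how often camera calls an unchanged list in the real libraries. Alternatives were DESeq2 1.42.0, limma-voom, median-ratio size factors, no filter on low counts, a 2-fold minimum, leaving out each library, replicate number or cell line, adding Detroit 562 to the joint fit, and taking a line's contrast from the 36-library fit. CPM of marker genes were computed per line without a test. No comparison of YAP with TAZ alone is possible, since every knockdown targeted both.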

Results

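RNA was sequenced from 7 human cancer cell lines 48 h after transfection with a non-targeting siRNA (siNTC) or with siRNAs against YAP and TAZ (siYAP/TAZ), in flat culture. YAP and TAZ, encoded by YAP1 and WWTR1, are the transcriptional coactivators that the Hippo kinase pathway holds in check, and they act mainly through TEAD transcription factors. Each line gave 3 siNTC and 3 siYAP/TAZ libraries, 42 libraries in all. Per the labels, Detroit 562 is a carcinoma line of the nasal pharynx, ES-2 an ovarian clear cell adenocarcinoma, HCC1954 a ductal adenocarcinoma of the breast, SF268 a glioma, RVH-421 a melanoma, SKG-II a large cell carcinoma of the cervix and OVCAR-8 an ovarian adenocarcinoma. Total counts per library ran from 21.2 M in SF268 to 52.3 M in Detroit 562. Within the groups, pairs of replicates had Pearson correlations of log2 CPM (counts scaled to library size), across genes, of at least 0.9944. The series title names Hippo pathway dependency across cancers, and the comparison asks which transcripts respond to loss of the pathway's effectors in each line. Below, CPM are means ± SD of 3 libraries and log2 fold changes (siYAP/TAZ over siNTC) are given ± SE. Verbs of change are used for what passed an adjusted p of 0.05. The p-values measure the difference against the spread between libraries of a group, and that spread may be technical, since the labels do not say whether replicates were separate transfections.

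Both siRNA targets fell in all 7 lines, to different degrees. YAP1 (Entrez 10413; chromosome 11, 102110447 to 102233424 in GRCh38.p14) fell from 1317 ± 17.0 to 108 ± 4.7 CPM in Detroit 562, so that 8.2% of the transcript remained. The remaining share of YAP1 was 8.1% in HCC1954, 9% in OVCAR-8, 12.8% in SF268, 13.3% in ES-2, 16.4% in RVH-421 and 31.6% in SKG-II. WWTR1 (Entrez 25937; chromosome 3, 149517235 to 149724788) was reduced to 13.7% in Detroit 562 and 13.6% in HCC1954, to 32.8% in SF268, 37.6% in OVCAR-8 and 41.2% in RVH-421. It was reduced least in SKG-II, where 63.2% remained, and in ES-2, where 82.3% remained (52.4 ± 0.87 against 43.2 ± 1.9 CPM; log2 fold change -0.28 ± 0.048, adjusted p = 2.2e-05). In every line, each siYAP/TAZ library lay below each siNTC library for both genes. The WWTR1 transcript started at very different levels, from 19.7 ± 0.90 CPM in OVCAR-8 to 303 ± 10.9 CPM in RVH-421. Transcript levels were measured and not protein, and ES-2 in particular is mainly a YAP1 knockdown at the level of RNA.

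**Figure D1:**
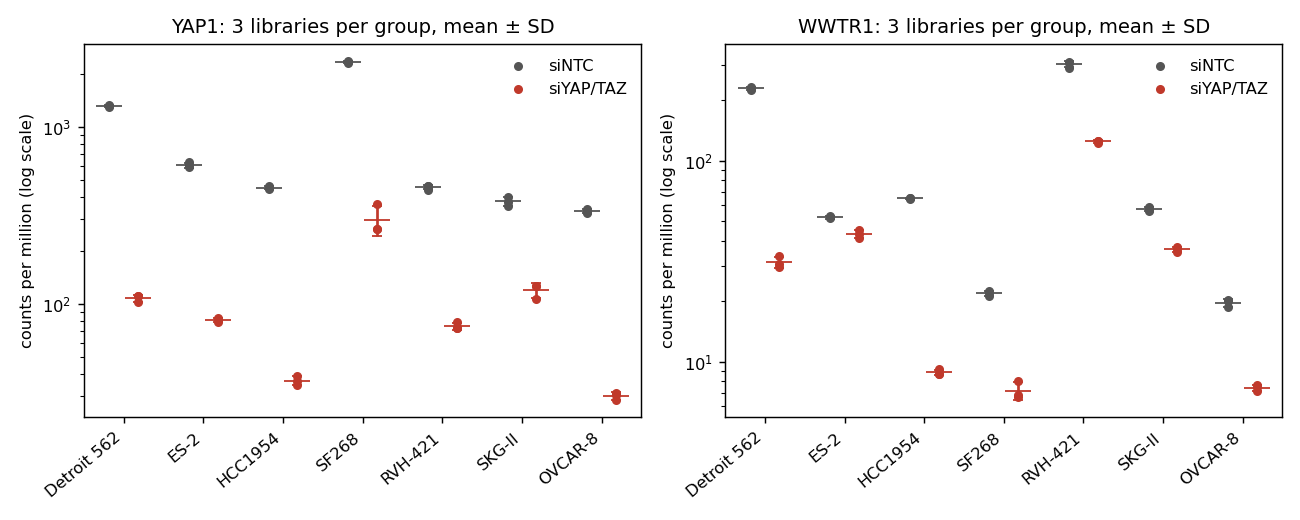
YAP1 (left) and WWTR1 (right) in CPM on a log axis, per library, for siNTC and siYAP/TAZ in each of the 7 lines; points are libraries (n = 3 per group), bars the mean ± SD. All siYAP/TAZ points lie below the siNTC points of the same line, with the smallest gap for WWTR1 in ES-2, where 82.3% remained.

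The known YAP/TAZ targets CCN1 and CCN2 fell in every line. The number of genes that passed the threshold ranged from 1944 in RVH-421 to 11416 in Detroit 562. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 11416 of 15790 genes tested passed in Detroit 562, 11162 of 16443 in OVCAR-8, 10403 of 15355 in ES-2, 7464 of 15670 in HCC1954, 7072 of 15914 in SKG-II, 5480 of 15205 in SF268 and 1944 of 15461 in RVH-421. Rises and falls were nearly balanced, for instance 5730 against 5686 in Detroit 562 and 1041 against 903 in RVH-421. TMM scaling centres the fold changes near 0 (medians over all genes from -0.007 in HCC1954 to 0.017 in SF268). It can largely set this balance, and a shift of most genes in one direction could not be seen. Most changes were small: 2652 genes moved at least 2-fold in Detroit 562, 2376 in OVCAR-8, 1667 in ES-2, 804 in SKG-II, 576 in HCC1954, 502 in SF268 and 96 in RVH-421. Among these larger changes, rises outnumbered falls in every line, from 336 against 240 in HCC1954 to 403 against 99 in SF268. Among genes with a mean of at least 10 CPM this turned to 63 rises against 74 falls in HCC1954 and 310 against 396 in OVCAR-8, and was 521 against 519 in Detroit 562. The 3 siNTC and 3 siYAP/TAZ values did not overlap for 74.7% of genes in Detroit 562 and 30.2% in RVH-421, where chance gives 10%. Leaving out siNTC replicate 3 or siYAP/TAZ replicate 2 of RVH-421 brought its count to 1102 or 950. Counts of calls also depend on the spread between libraries, which differed by line. edgeR's common coefficient of variation was 0.0601 in RVH-421 and 0.0608 in SF268, against 0.0442 in Detroit 562. It was 0.0576 in OVCAR-8, where 11162 genes passed. The part of the spread in the differences between these counts was not tested.

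**Figure D2:**
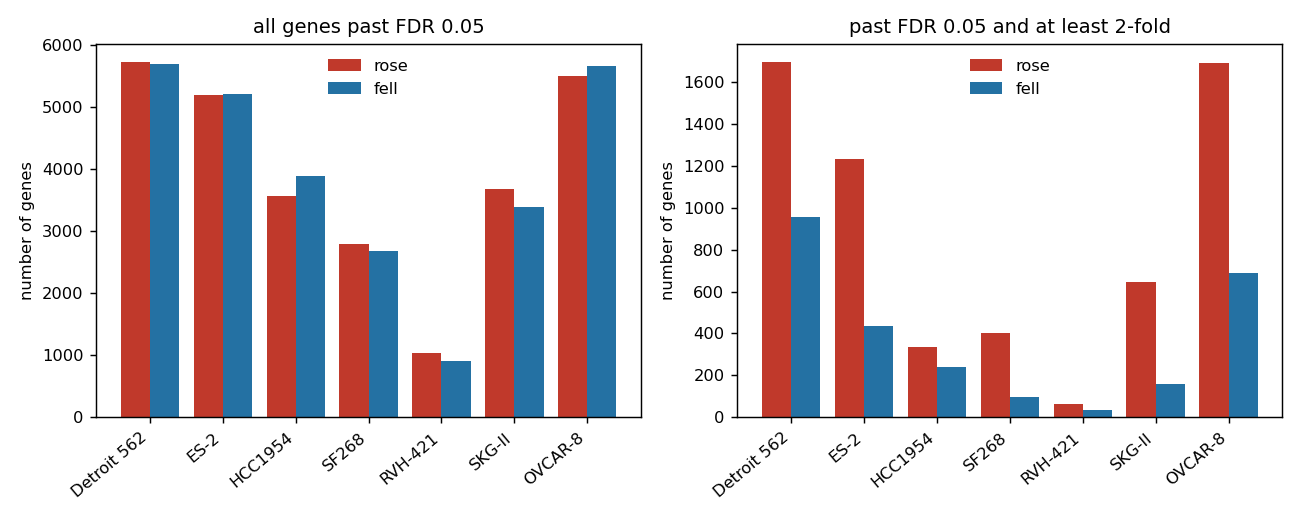
Number of genes that rose (red) or fell (blue) with siYAP/TAZ in each line, for all genes past an adjusted p of 0.05 (left) and for those that also moved at least 2-fold (right). Detroit 562 has 5730 rises and 5686 falls, RVH-421 has 1041 and 903, and at 2-fold or more the rises outnumber the falls in all 7 lines, with genes of any CPM counted.

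Gene groups were compared with 18 lists fixed before the data were examined, tested with limma's camera against all other genes of the line. Camera was run with a small preset correlation between genes (0.01), which called 69 of 126 line-and-list combinations. With the correlation estimated from the 6 libraries of a line, 5 held. Estimating it raised p even where the estimate lay below the preset value. For the interferon list in ES-2 the estimate was -0.0302, and the camera p went from 2.61e-06 to 0.00685. A lost call therefore does not show that a list stayed level. When the group labels were reassigned at random within lines, the preset test still called up to 55 combinations, with a median of 38. A reassigned line kept either its real grouping or an uneven mix of the treatments, so part of the treatment effect stayed. These numbers are therefore not a rate of false calls, and that rate is unknown. A call of a single list in a single line is taken as weak evidence by itself, and the estimated-correlation p is given beside it. In each account, members that moved against the direction of their list, or that did not pass, were named after their values were seen.

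In Detroit 562, the YAP/TAZ target list fell as a group with the preset correlation, and so did genes of DNA replication and the actin cytoskeleton, while interferon-response genes rose. With an estimated correlation none of these calls held (adjusted p = 0.285, and 0.318 for the interferon list). CCN2, which encodes the matricellular protein CTGF, fell from 138 ± 4.5 to 8.8 ± 1.1 CPM (log2 fold change -3.96 ± 0.069), and CCN1, its relative also known as CYR61, fell by 3.35 ± 0.043 on the log2 scale. ANKRD1, a cardiac ankyrin repeat protein, fell by 3.51, and F3, which encodes tissue factor, by 2.41. Of the 22 targets, 20 fell and 2 rose, IGFBP3 (1.28) and CCDC80 (0.52), with the same counts when adjusted over the list alone; the median was -1.11. Camera put this list at an adjusted p of 3.42e-07, and at an adjusted p = 0.285 with an estimated correlation. The angiogenesis inhibitor THBS1 fell from 4784 ± 57 to 384 ± 45 CPM. The largest falls by the naming rule also took in the RNA-binding protein RBM24 (-4.78 ± 0.22), the BMP antagonist NOG (-3.75 ± 0.16) and SH2D5 (-3.69 ± 0.098). The largest rises were MMP12, the macrophage elastase (0.55 ± 0.29 to 31.9 ± 3.4 CPM, on 62 control reads), the mucin-type glycosyltransferase GCNT3 (5.40 ± 0.12), the transcription factor SOX21 (4.83 ± 0.085), AKR1C2 (4.79 ± 0.099) and TCIM (4.51 ± 0.10). AKR1C2 is an aldo-keto reductase with near-identical relatives, and single-end reads of this length may be split among them. All 24 interferon-response genes rose (median 1.26; camera adjusted p = 3.42e-07, adjusted p = 0.318 with an estimated correlation), among them OAS2 (2.16 ± 0.083), OASL (2.08 ± 0.058) and the transcription factor IRF9 (1.85 ± 0.072). DNA replication genes fell in 34 of 39 cases, including the helicase subunit MCM2 (-0.84), the licensing factor CDC6 (-0.88) and UHRF1 (-1.33), while CCNE2 rose and 4 did not pass; the camera adjusted p was 1.29e-07, and the adjusted p = 0.285 with an estimated correlation. Of 26 actin and adhesion genes, 20 fell, such as ACTN1 (-1.09) and the filamin FLNA (-1.14), and TPM2, ITGA5 and ITGAV rose. For that list, the camera adjusted p was 0.000194, with an adjusted p = 0.285 with an estimated correlation. Of 21 p53 targets, 14 rose, with TP53INP1 at 4.03 ± 0.093, BTG2 at 2.15 and the cell cycle inhibitor CDKN1A at 1.27, and 5 fell, with AEN, a nuclease, at -1.61. As a group these had a camera adjusted p of 0.0268, and an adjusted p = 0.285 with an estimated correlation. Single genes of other lists moved far: the cytokines IL1A (-3.45) and IL1B (-3.17) and the AP-1 subunit FOSL1 fell, and the epithelial transcription factor ELF3 rose by 1.97 ± 0.042.

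In ES-2, the targets and mitotic genes fell as lists with the preset correlation, and genes of MAPK output, actin and adhesion, and the extracellular matrix rose. None of these calls held with an estimated correlation (adjusted p from 0.178 to 0.389). ANKRD1 fell from 729 ± 24 to 49.8 ± 2.1 CPM (-3.87 ± 0.044), CCN2 by 2.38 and CCN1 by 1.68. Of 22 targets, 17 fell, LATS2 did not pass, and GADD45A, NT5E, PTPN14 and ARHGEF17 rose (median -0.61; camera adjusted p = 0.000165, adjusted p = 0.19 with an estimated correlation). All 36 mitosis genes fell (median -0.60), among them the cytokinesis scaffold ANLN (-0.99 ± 0.035), cyclin B1 (CCNB1, -0.96) and the anaphase activator CDC20 (-0.93), with a camera adjusted p of 1.15e-11 and an adjusted p = 0.178 with an estimated correlation. Of 10 MAPK output genes, which report signalling through the RAS and ERK cascade, 8 rose: the phosphatases DUSP4 (2.46 ± 0.041) and DUSP6 (1.39 ± 0.039), PHLDA1 (1.12) and the feedback inhibitor SPRY4 (0.97) led, and SPRY2 and EPHA4 did not pass. The list's camera adjusted p was 0.000543, and the adjusted p = 0.19 with an estimated correlation. Actin and adhesion genes rose in 19 of 26 cases, with the integrin subunits ITGA5 (1.47) and ITGB5 (1.48) at the top, while CNN3 fell by 1.10, as did VCL, TPM4 and SRF by less. Tested together, they gave a camera adjusted p of 0.0108 and an adjusted p = 0.326 with an estimated correlation. Of 17 matrix genes, 14 rose, with laminin LAMA5 at 2.86 ± 0.052 and fibronectin, FN1, at 1.42, and the lysyl oxidase LOX fell by 1.96. Against all other genes, the camera adjusted p was 0.00144, and the adjusted p = 0.389 with an estimated correlation. Interferon-response genes rose in 17 of 20 cases (median 1.01; IFIT2 2.18, IRF9 1.94), HERC5 fell, and the adjusted p = 0.123 with an estimated correlation against 1.57e-05 with the preset one. Outside the lists, the vasoconstrictor peptide EDN1 fell from 64.6 ± 1.2 to 2.8 ± 0.51 CPM, and LINC01111 (-5.79 ± 0.19), KCTD4 (-4.83 ± 0.15) and SERPINB7 (-3.82 ± 0.065) fell with it. The largest rises began from few control reads: ITGA11, a collagen-binding integrin (6 reads over 3 libraries; 0.059 ± 0.0075 to 9.1 ± 0.085 CPM), the protease inhibitor SERPINA3 (18 reads; 6.39 ± 0.17), CD96 (24 reads; 5.48 ± 0.18) and CSF1R (15 reads; 5.25 ± 0.21). BMF, a pro-apoptotic member of the BCL2 family, rose from 0.89 ± 0.083 to 31.8 ± 0.59 CPM.

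HCC1954 held the receptor ERBB2 at 7870 CPM and its chromosomal neighbour GRB7 at 1690 CPM in the siNTC libraries, and each of the 21 measured YAP/TAZ targets fell. ANKRD1 fell by 4.73 ± 0.22, CCN2 by 3.82 ± 0.072 (70.2 ± 3.0 to 5.0 ± 0.070 CPM), CCN1 by 2.94 ± 0.049 and the growth factor TGFB2 by 2.16 ± 0.051. The list median was -0.84. Camera put this list at an adjusted p of 1.16e-15, and at an adjusted p = 0.129 with an estimated correlation. Of 25 Hippo pathway and TEAD genes, 17 fell, such as AJUBA (-1.98), AMOTL2 (-1.79) and WWC2 (-1.20), TAOK2, AMOT and TEAD3 rose, and 5 did not pass; 19 fell and 5 rose when adjusted over the list alone. For that list, the camera adjusted p was 2.69e-05, with an adjusted p = 0.129 with an estimated correlation. Matrix genes fell in 8 of 17 cases, with THBS1 at -2.70 ± 0.045 and the collagen COL12A1 at -2.26, while COL1A1, COL4A1 and TNC rose. The matrix call (camera adjusted p = 0.00793, adjusted p = 0.318 with an estimated correlation) ended without siYAP/TAZ replicate 3 (0.0555). Of 39 DNA replication genes, 30 fell, among them the ribonucleotide reductase subunit RRM1 (-0.65) and GINS2 (-0.53), E2F2 rose, and this list kept its call with an estimated correlation (adjusted p = 0.0488). Of 21 growth factor ligands and receptors, 12 fell, with the receptors MET at -1.09 and FGFR2 at -1.83, and BTC and ERBB3 rose. As a group these had a camera adjusted p of 0.0112, and an adjusted p = 0.254 with an estimated correlation. Interferon-response genes rose in 12 of 24 cases, with IRF9 at 0.80 ± 0.057 and OASL at 0.70. The list's camera adjusted p was 0.000115, and the adjusted p = 0.478 with an estimated correlation. The chemokine CCL2 fell by 2.02 and the mesenchymal transcription factor SNAI2 by 1.41. Rises were led by DMBT1, a mucin-like scavenger protein (3.4 ± 0.67 to 23.1 ± 0.26 CPM; 2.76 ± 0.10), the cornified envelope protein SPRR1A (2.27 ± 0.17), the glucose transporter SLC5A1 (2.26 ± 0.13), TSPAN8 (2.22 ± 0.13) and NCALD (2.09 ± 0.16).

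SF268 held YAP1 at 2327 ± 37 CPM in the control and lost replication transcripts broadly, with 36 of 39 falling and POLE2, E2F2 and CCNE1 not passing. RRM1 fell by 0.99 ± 0.055, CDC6 by 0.82 ± 0.057 and thymidylate synthase, TYMS, by 0.63; the list median was -0.49. Tested together, they gave a camera adjusted p of 3.26e-16 and an adjusted p = 0.149 with an estimated correlation. Of 22 targets, 13 fell (15 when adjusted over the list alone), DOCK5 rose and 8 did not pass, with CCN1 at -1.51 ± 0.061, ANKRD1 at -1.24 and F3 at -1.18. Against all other genes, the camera adjusted p was 7.53e-08, and the adjusted p = 0.238 with an estimated correlation. Glycolysis genes fell in 14 of 20 cases, including hexokinase HK2 (-0.70), the glucose transporter SLC2A1 (-0.58) and lactate dehydrogenase LDHA (-0.41), and none rose. Camera put this list at an adjusted p of 1.2e-05, and at an adjusted p = 0.354 with an estimated correlation. Of 17 interferon-response genes, 13 rose, such as IFI44 (1.22 ± 0.15) and IFI44L (2.51 ± 0.32). For that list, the camera adjusted p was 5.45e-05, with an adjusted p = 0.149 with an estimated correlation. Of 20 p53 targets, 10 rose, with BTG2 at 0.89 and TP53I3 at 0.62, and AEN and TNFRSF10B fell. As a group these had a camera adjusted p of 0.0153, and an adjusted p = 0.238 with an estimated correlation. The natriuretic peptide NPPB fell from 136 ± 8.7 to 36.4 ± 2.5 CPM, and the long noncoding RNA PTCSC3 (-1.90 ± 0.11) and the phosphatase PTPRQ (-2.26 ± 0.17) fell as well. PLCE1-AS1 fell by 2.45 ± 0.12, but it lies antisense to PLCE1 and the library kit does not mark strand, so its reads cannot be told from those of its partner. BMF rose by 2.69 ± 0.18, followed by TRANK1 (2.11 ± 0.16), the noncoding RNA MIAT (2.03 ± 0.19), ankyrin ANK1 (1.99 ± 0.17) and the cytochrome CYP1B1 (1.99 ± 0.099). The MAPK output list, with 5 falls led by DUSP4 at -0.94 and rises of PHLDA1 and EPHA4, had a camera adjusted p of 0.0496 and an adjusted p = 0.338 with an estimated correlation; it passed 0.05 no longer with median-ratio scaling (0.0554) or without any of 4 libraries (siNTC replicate 1, 0.0534, or 3, 0.0572; siYAP/TAZ replicate 1, 0.0946, or 3, 0.0575). The actin and adhesion list (11 of 26 fell, CALD1 by 0.63; camera adjusted p = 0.0222, adjusted p = 0.468 with an estimated correlation) was at 0.138 without siYAP/TAZ replicate 1.

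RVH-421 had the fewest calls of the 7 lines, and cell division genes were prominent among them. Its siNTC libraries held the melanocyte enzymes DCT at 2630 CPM and TYR at 1420 CPM and the transcription factor SOX10 at 702 CPM, which were under 1 CPM in the other 6 lines. Of 36 mitosis genes, 35 fell (CDC20 by 0.72 ± 0.055, ANLN by 0.62 ± 0.053, KIF20A by 0.58) and CDK1 did not pass; this list passed with both the preset correlation (camera adjusted p = 2.03e-23) and the estimated one (adjusted p = 0.0193). DNA replication genes fell in 33 of 39 cases, 37 when adjusted over the list alone, with RRM1 at -0.71 ± 0.057 and TYMS at -0.58 (adjusted p = 0.0103 with an estimated correlation). Of 23 cholesterol synthesis genes, 8 fell (15 when adjusted over the list alone) and none rose, for example EBP (-0.38) and FDPS (-0.32), with an adjusted p = 0.0323 with an estimated correlation. YAP/TAZ targets fell in 9 of 21 cases: CCN1 by 1.74 ± 0.14, AMOTL2 by 1.11 ± 0.077, MYOF by 1.11 ± 0.092 and CCN2 by 0.96 ± 0.10, while CCDC80 and RBMS3 rose and 10 did not pass. The list's camera adjusted p was 2.69e-06, and the adjusted p = 0.294 with an estimated correlation. Interferon-response genes rose in 6 of 21 cases (9 when adjusted over the list alone), with ISG15 at 1.10 ± 0.16 and CMPK2 at 0.85 ± 0.19, and the median was 0.18 (adjusted p = 0.0416 with an estimated correlation). The chemokine CXCL1 fell by 1.49 ± 0.070 on the log2 scale, the matrix protein EFEMP1 by 2.04 ± 0.11 and PSG4, a pregnancy-specific glycoprotein from a family of similar genes, by 1.67 ± 0.16. Rises were led by PDK4, a kinase that restrains pyruvate oxidation (6.8 ± 0.61 to 24.3 ± 1.4 CPM; 1.84 ± 0.089), RTN4RL1 (1.55 ± 0.12), the guidance factor SEMA3D (1.46 ± 0.063), TMEM255A (1.44 ± 0.11) and RASGRP3 (1.37 ± 0.099). The matrix list (7 of 19 fell, LOX by 0.72; camera adjusted p = 0.0236, adjusted p = 0.658 with an estimated correlation) and the glycolysis list (3 of 20 fell; 0.0277, and adjusted p = 0.658 with an estimated correlation) rose above 0.05 without siNTC replicate 1 or 3 or siYAP/TAZ replicate 3, up to 0.204 and 0.201. The BCL2 family list (6 of 13 rose, BMF by 1.37; camera adjusted p = 0.035, adjusted p = 0.237 with an estimated correlation) was at 0.0649 without siNTC replicate 2.

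In SKG-II, where 31.6% of YAP1 remained, the preset-correlation test called falls of the targets and mitotic genes and rises of inflammatory and interferon genes. These calls ended with an estimated correlation (adjusted p from 0.157 to 0.447). CCN1 fell from 2050 ± 35 to 583 ± 32 CPM (-1.81 ± 0.057), CCN2 by 1.64 ± 0.062 and CRIM1 by 1.13. Of 22 targets, 20 fell, and NT5E and PTPN14 rose (median -0.83; camera adjusted p = 9.25e-11, adjusted p = 0.157 with an estimated correlation). All 36 mitosis genes fell, led by CDC20 (-0.63), ANLN (-0.63) and KIF23 (-0.57), with a camera adjusted p of 1.15e-11 and an adjusted p = 0.21 with an estimated correlation. NF-kB and chemokine genes rose in 13 of 17 cases (15 when adjusted over the list alone), with the neutrophil chemokine CXCL8 at 2.50 ± 0.13, the kinase IRAK2 at 2.26, the apoptosis inhibitor BIRC3 at 2.09 and the NF-kB inhibitor NFKBIA at 1.02, and IL6 fell. Tested together, they gave a camera adjusted p of 3.55e-07 and an adjusted p = 0.21 with an estimated correlation. Of 23 interferon-response genes, 21 rose, such as OASL (2.30 ± 0.086), IFIH1 (1.09) and RIGI (1.06), the latter pair being cytoplasmic RNA sensors. Against all other genes, the camera adjusted p was 8.11e-09, and the adjusted p = 0.447 with an estimated correlation. Glycolysis genes rose in 14 of 20 cases, with PFKFB4 at 1.12 and ENO2 at 0.92, and PFKM fell. Camera put this list at an adjusted p of 0.00217, and at an adjusted p = 0.583 with an estimated correlation. Of 20 p53 targets, 14 rose and none fell, with BTG2 at 0.79 and DDB2 at 0.61. For that list, the camera adjusted p was 0.000212, with an adjusted p = 0.157 with an estimated correlation. DNA replication genes moved little: 14 of 39 fell, with RRM1 at -0.51, while 3 rose and 22 did not pass. As a group these had a camera adjusted p of 0.0188, and an adjusted p = 0.456 with an estimated correlation. The largest rises were the cytokine LTB and the gelatinase MMP9, from 14 and 10 control reads to 8.2 ± 1.7 and 5.6 ± 0.77 CPM, then the hypoxia-associated carbonic anhydrase CA9 (3.81 ± 0.11), ANKRD22 (3.65 ± 0.17) and the death ligand TNFSF10, or TRAIL (7.6 ± 0.72 to 89.9 ± 7.0 CPM). NPPB (-2.18 ± 0.097), STXBP6 (-2.11 ± 0.097), the chloride channel ANO2 (-1.99 ± 0.092) and VSTM1 (-1.89 ± 0.099) fell.

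OVCAR-8 had deep falls of several YAP/TAZ targets and a steep rise of BMF. IGFBP3, an insulin-like growth factor binding protein, fell from 383 ± 23 to 7.3 ± 0.56 CPM (-5.71 ± 0.077), ANKRD1 from 829 ± 65 to 18.3 ± 1.6 CPM and CCN2 from a mean of 151.5 to 6.354 CPM, or 23.8-fold. Of 22 targets, 18 fell and none rose, while FOXF2, NT5E, PTPN14 and RBMS3 did not pass (median -1.29; camera adjusted p = 7.26e-08, adjusted p = 0.0789 with an estimated correlation). BMF rose from 0.30 ± 0.076 CPM, 25 reads over 3 libraries, to 90.1 ± 1.4 CPM (8.20 ± 0.11), and its relative BCL2L11, or BIM, rose by 2.14 ± 0.085, while the anti-apoptotic BCL2L1 fell by 1.09 ± 0.060. The retinol transporter STRA6 and the retinal reductase DHRS3 rose from 9 and 26 control reads to 18.1 ± 1.4 and 27.6 ± 0.82 CPM; GASK1B and ANXA10 rose from 8 and 4 control reads to 20.1 ± 0.37 and 5.9 ± 0.69 CPM. Interferon-response genes rose in 18 of 21 cases. IFIT2 was up 4.05 ± 0.083, OASL 3.85 ± 0.084 and IFIT3 2.71 ± 0.078 (median 1.54; camera adjusted p = 7.26e-08, adjusted p = 0.0577 with an estimated correlation). Of 24 cholesterol synthesis genes, 22 fell, with ACAT2 at -1.27, HMGCS1 at -1.15 and SQLE at -1.07. The list's camera adjusted p was 2.56e-06, and the adjusted p = 0.122 with an estimated correlation. Mitosis genes fell in 32 of 36 cases, with ANLN at -1.17 ± 0.052. Tested together, they gave a camera adjusted p of 1.27e-07 and an adjusted p = 0.122 with an estimated correlation. MAPK output genes fell in 8 of 10 cases, with the ephrin receptor EPHA2 at -1.99 and cyclin D1, CCND1, at -1.81, and PHLDA1 and SPRY2 rose. Against all other genes, the camera adjusted p was 0.0227, and the adjusted p = 0.173 with an estimated correlation. Actin and adhesion genes fell in 21 of 27 cases, with TAGLN at -1.82 and LIMA1 at -1.62, and ITGA5, ITGAV, ITGB5 and ACTA2 rose. Camera put this list at an adjusted p of 0.000406, and at an adjusted p = 0.28 with an estimated correlation. The AP-1 subunits FOSL1 and MAFF fell by 2.05 and 2.28 and JUNB rose by 1.75 ± 0.069. The keratin-associated KRTAP2-3, of a family of near-identical genes, fell by 5.86 ± 0.27, ANO2 by 5.30 ± 0.23 and the transcribed pseudogene SFTA1P by 5.50 ± 0.15.

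Across lines, 335 of 12344 genes tested in all 7 were called in the same direction everywhere, 198 falling and 137 rising, where independent lists of these sizes would give 0.5 and 0.2. The lines have no libraries in common, so no shared control adds to this overlap. They do share the siRNA design, and effects of the siRNAs other than loss of YAP and TAZ could also recur in every line. This was not tested. The expected numbers treat all genes as equally likely to be called, which well-expressed genes are not. Besides both siRNA targets, the shared genes with the largest mean change were BMF (mean log2 fold change 3.76, from 1.37 to 8.20 over lines), CCN2 (-2.61), CCN1 (-2.27), the aldo-keto reductase AKR1C3 (2.18, from a family of similar sequences), the methyltransferase-like TMT1A (2.05), the PI3K inhibitor PIK3IP1 (1.93, from 1.09 to 2.72), the aldehyde oxidase AOX1 (-1.68) and the angiomotin relative AMOTL2 (-1.62). Of the target list, CCN2, CCN1, AMOTL2, FJX1 and CRIM1 fell in all 7 lines. DNA replication and mitosis each gave 12 genes that fell in all 7, among them RRM1, MCM10, CDC6 and CDC45, and ANLN, CDC20, AURKA and FOXM1. ITGA5, CNN3, JUNB, TP53I3, IFIH1, PPP1R15A, TEAD4 and WWC2 were the other list members with a single direction in all lines; of these the falling ones were CNN3, PPP1R15A, TEAD4 and WWC2. The count depends strongly on library number: with 2 libraries per group, leaving out replicate 1, 2 or 3 of every group, it was 166, 118 or 128. On leaving out 1 RVH-421 library, AKR1C3 (adjusted p = 0.0565), AOX1 (0.0665), JUNB (up to 0.0835) and TP53I3 (0.0501) no longer passed in that line. In at least 6 of the 7 lines, 1700 genes shared a direction, where 23.2 are expected from independent lists.

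**Figure D3:**
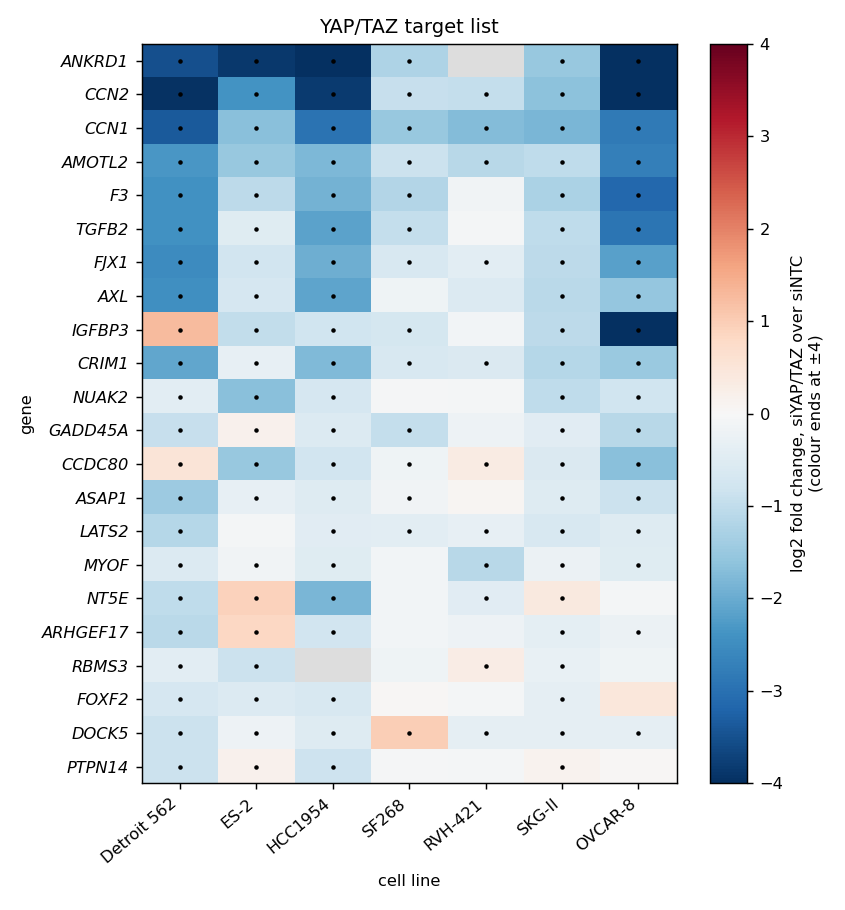
Log2 fold change (siYAP/TAZ over siNTC) of the 22 YAP/TAZ target genes in the 7 lines; blue is a fall, red a rise, grey not tested, and a dot marks an adjusted p under 0.05. CCN2, CCN1, AMOTL2, FJX1 and CRIM1 carry a dot and a blue cell in all 7 lines.

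Averaged over the 6 lines that were deposited together (all but Detroit 562), 10736 of 19459 genes passed, 5658 rising and 5078 falling, of which 523 and 114 moved at least 2-fold. The SE of such an average measures the spread between libraries and not between lines. IGFBP3, at -1.55 ± 0.023, ran from -5.68 to -0.111 over the lines, and BMF from 1.37 to 8.23. A gene with 1 sign in all 6 lines may also have hardly moved in a line. In RVH-421, IFI44L was at 0.025, GBP2 at 0.039 and ADAMTS1 at -0.042. Among genes with 1 sign in all 6 lines and at least 5 CPM in at least 3 of them, BMF rose most (3.73 ± 0.044), followed by STRA6 (3.26 ± 0.24), PLAAT4, a phospholipase also called RARRES3 (2.32 ± 0.085), SYTL5 (2.29 ± 0.21), IFI44L (2.21 ± 0.29), OAS2 (2.12 ± 0.50), the ISG15-activating enzyme UBA7 (2.12 ± 0.052), TMT1A (2.07 ± 0.12), the interferon-inducible GTPase GBP2 (1.97 ± 0.043) and TRANK1 (1.94 ± 0.070). The largest falls of such genes were SFTA1P (-3.14 ± 0.82), YAP1 (-2.86 ± 0.033), CCN2 (-2.37 ± 0.027), EDN1 (-2.24 ± 0.56), CCN1 (-2.07 ± 0.027), LINC00707 (4.01-fold), the ubiquitin ligase MARCHF4 (-1.82 ± 0.22), the metalloprotease ADAMTS1 (-1.56 ± 0.060), IGFBP3 (-1.55 ± 0.023) and PSG4 (-1.54 ± 0.11). The calls of SFTA1P (adjusted p = 1 without replicate 2), EDN1 (1 without replicate 1) and OAS2 (0.056 without replicate 2) were lost with 2 libraries per group. The mean log2 fold changes were then still -2.75 for SFTA1P and -1.96 for EDN1. A line left without reads of the gene would also give such a p, and whether this was so was not tested. In this 36-library fit, in a list test added after the data were seen, camera with an estimated correlation kept the falls of the YAP/TAZ targets (21 of 22 fell), DNA replication (36 of 39), mitosis (36 of 36) and cholesterol synthesis (22 of 24), each at an adjusted p of 0.00607, and the rise of NF-kB and chemokine genes (11 rose and 2 fell of 20; adjusted p = 0.0188). Single lines did not all follow these averages. With the preset correlation the cholesterol list was called as falling in 4 of the 7 lines and the NF-kB list as rising in 4. In HCC1954, 9 cholesterol synthesis genes rose and 2 fell, and SKG-II had 2 of each. The NF-kB median was 0.026 in HCC1954 and -0.022 in RVH-421. Interferon-response genes rose in 22 of 24 cases with a median of 0.96. For that list, the camera adjusted p was 4.41e-10, with an adjusted p = 0.0549 with an estimated correlation. The Hippo (16 of 25 fell; camera adjusted p = 0.000715, adjusted p = 0.163 with an estimated correlation), actin (20 of 27 fell; 0.000439; adjusted p = 0.163 with an estimated correlation) and p53 target lists (13 of 21 rose; 0.0302; adjusted p = 0.0794 with an estimated correlation) lost their calls with an estimated correlation. The AP-1, glycolysis, growth factor, BCL2 family, epithelial, mesenchymal, matrix, MAPK output and ER stress lists gave camera adjusted p from 0.107 to 0.99 on this average.

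**Figure D4:**
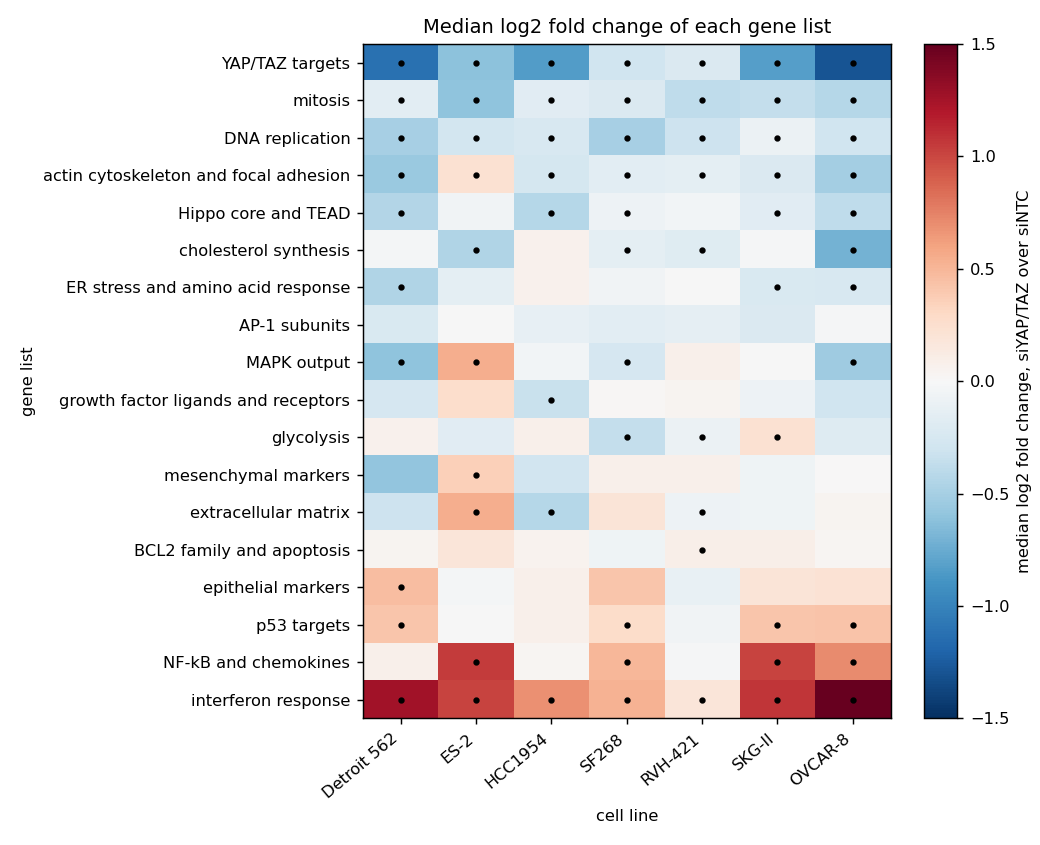
Median log2 fold change of each of the 18 gene lists (vertical) in each of the 7 lines (horizontal), with the colour running from blue (fall) to red (rise) and a dot for a camera adjusted p under 0.05 with the preset correlation. The YAP/TAZ target, DNA replication and mitosis lists are blue with a dot in all 7 lines and the interferon response list is red with a dot in all 7. With an estimated correlation, 0, 2, 1 and 1 of the 7 calls of these lists held. The actin and MAPK output lists are red in ES-2, where their medians are 0.23 and 0.54.

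The response differed between lines for most genes. The depth of the knockdown differed as well. YAP1 left ran from 8.1% in HCC1954 to 31.6% in SKG-II, and WWTR1 left from 13.6% in HCC1954 to 82.3% in ES-2. Unequal knockdown can be part of any difference given here and was not separated from other differences between the lines. The 5 differences between the 6 within-line fold changes were past the threshold for 12530 of 19459 genes (64.4%), and in 4883 of them the lines also lay at least 2-fold apart, a measure added after the data were seen. IGFBP3 had the largest F (1060), from -0.11 in RVH-421 to -5.68 in OVCAR-8. The vasodilator peptide ADM was at 2.32 in ES-2 and at -4.38 in OVCAR-8 (F = 481), and the integrin subunit ITGA1 was at 3.22 in ES-2 and -1.33 in HCC1954 (F = 369). The cell cycle inhibitor CDKN2B was at 3.84 in ES-2 and between -0.12 and 0.73 in 4 other lines, and SF268 had no reads of it (F = 517). DHRS3, at 6.47 in OVCAR-8 and 3.36 in ES-2, was at -0.46 in RVH-421. Set against the mean of the other 5 lines, 52 of 108 line-and-list tests passed with the preset correlation. Of these, 16 passed with an estimated one. Random relabelling, which left part of the treatment effect in place, gave up to 42 with the preset correlation. In ES-2, MAPK output genes stood 0.87 higher than in the other lines (median of the differences; adjusted p = 0.00178 with an estimated correlation). Targets fell further in HCC1954 (-0.56; adjusted p = 0.0298 with an estimated correlation) and less in SF268 (0.40; adjusted p = 0.0148 with an estimated correlation) and RVH-421 (0.51; adjusted p = 0.0357 with an estimated correlation) than in the mean of the other 5 lines. In OVCAR-8 this difference was -0.58, with a camera adjusted p of 2.97e-09 and an adjusted p = 0.0517 with an estimated correlation. Cholesterol synthesis genes stood lower in OVCAR-8 (-0.49; adjusted p = 0.00178 with an estimated correlation) and higher in HCC1954 (0.34; adjusted p = 0.00119 with an estimated correlation), and NF-kB and chemokine genes stood higher in SKG-II (0.40; adjusted p = 0.00119 with an estimated correlation).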

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

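These results stand here because the effect of siYAP/TAZ differed between cell lines by a test of the difference. The depth of the knockdown differed between the lines as well, and its part in these differences was not separated. The tests of the interferon-response list and of TAZ left after the knockdown were chosen after the results were seen.

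Over the 6 lines fitted together, 12530 genes had fold changes that differed between lines. The strongest were IGFBP3 (F = 1060), CDKN2B (517), DHRS3 (513), CCN2 (505), ANKRD1 (487), ADM (481), BMF (466), GNG2 (388), JAG1 (382) and ITGA1 (369).

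Lists that stood apart in a line are given as the median difference from the mean of the other 5 lines, all past the preset-correlation test. In ES-2 these were MAPK output (0.87), extracellular matrix (0.80), actin and adhesion (0.50), growth factors (0.40), mesenchymal markers (0.40), YAP/TAZ targets (0.39), Hippo genes (0.24), AP-1 (0.23), cholesterol synthesis (-0.25) and mitosis (-0.32). In HCC1954 they were cholesterol synthesis (0.34), ER stress (0.25), mitosis (0.22), glycolysis (0.20), DNA replication (0.08), actin and adhesion (-0.09), Hippo genes (-0.23), extracellular matrix (-0.44), mesenchymal markers (-0.44), interferon response (-0.46), YAP/TAZ targets (-0.56), NF-kB (-0.58) and growth factors (-0.60). SF268 had YAP/TAZ targets (0.40), mitosis (0.18), cholesterol synthesis (0.14), BCL2 family (-0.16), interferon response (-0.17), DNA replication (-0.24), glycolysis (-0.26) and MAPK output (-0.28). RVH-421 had YAP/TAZ targets (0.51), Hippo genes (0.17), p53 targets (-0.20), NF-kB (-0.70) and interferon response (-0.73). SKG-II had NF-kB (0.40), glycolysis (0.31), interferon response (0.28), DNA replication (0.21), cholesterol synthesis (0.21), p53 targets (0.19), YAP/TAZ targets (0.13) and ER stress (-0.22). OVCAR-8 had interferon response (0.87), p53 targets (0.34), ER stress (-0.17), Hippo genes (-0.23), actin and adhesion (-0.25), cholesterol synthesis (-0.49), YAP/TAZ targets (-0.58) and MAPK output (-0.68). With an estimated correlation 16 of these 52 passed: MAPK output in ES-2 and OVCAR-8, YAP/TAZ targets in HCC1954, SF268 and RVH-421, NF-kB in HCC1954, RVH-421 and SKG-II, cholesterol synthesis in HCC1954, SKG-II and OVCAR-8, DNA replication in SF268 and SKG-II, ER stress and mesenchymal markers in HCC1954, and p53 targets in RVH-421. The others ran from 0.0517 to 0.559 and were lost.

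Random grouping of libraries was set against the counts. In single lines the 10 splits are too few for a share under 0.05: the real counts were 11416 (Detroit 562), 10403 (ES-2), 7464 (HCC1954), 5480 (SF268), 1944 (RVH-421), 7072 (SKG-II) and 11162 (OVCAR-8), and the highest other split gave 0 in each. For genes shared by 7 lines it was 335 against 0, which decides nothing because every other split of a line called 0 genes. The real split ranked 1 for the 6-line average (10736 against at most 3320) and for the differences between lines (12530 against at most 3505). The median of the other draws was 0 in both. In each draw a line could keep its real grouping, in either direction, so the highest counts need not come from random grouping. Otherwise relabelling mixes the treatments within a group and so widens its spread, which lowers the counts. Neither comparison therefore decides it. For lists the real totals also ranked 1, with 69 against at most 55 (median 38) per line. Between lines it was 52 against at most 42 (median 27.5). No relabelling reached these totals. The draws mixed the treatments in the same way, so this decides nothing for the totals or for any single list.

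The interferon-response list rose in all 7 lines with the preset correlation, while with an estimated one RVH-421 passed (adjusted p = 0.0416) and the other 6 lines ran from 0.0577 to 0.478. Members outside the IFIT, OAS, MX and IFI families had a mean of line medians of 0.69 (SE 0.126), so reads shared between gene copies are excluded as the whole cause. The list median was above 0 in 7 lines, which sensing of the siRNA duplexes might also give. The siNTC libraries received an siRNA too, so such sensing would have to differ between siNTC and siYAP/TAZ. Without untransfected or single-siRNA groups this cannot be told, and an untransfected group alone would not separate it from loss of YAP and TAZ. Across the 7 lines the interferon median ran against the YAP/TAZ target median (Spearman rho = -0.89, permutation p = 0.0123; Pearson r = -0.92, permutation p = 0.00476; over 17 relations the Benjamini-Hochberg values are 0.135 and 0.0809). RVH-421 and SF268 had the target medians farthest from the median over the lines. Both lie at the end of the smallest falls, at -0.217 and -0.302. Without them r was -0.76 over 5 lines (permutation p = 0.142), so loss of YAP and TAZ cannot be told from other causes either.

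Rises of at least 2-fold outnumbered falls in every line, but among genes with at least 10 CPM falls outnumbered rises in HCC1954 (74 against 63) and OVCAR-8 (396 against 310). The median share of rises was 71.2% with median-ratio scaling, which hardly moved the fold changes (by -0.009 to 0.007 in the median), so scaling between libraries cannot be told. Among genes with at least 10 CPM that share was 60.4%, with lines from 43.9% to 76%, so a floor that hides falls of low genes may be part of it but cannot be told. Summed olfactory receptor reads, a proxy for background, had a median log2 ratio of 0.36 but -0.88 in ES-2 and -1.04 in OVCAR-8, which cannot tell either. No biological explanation was tested.

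Among the 7 lines, the MAPK output list rose in ES-2 alone with the preset correlation (adjusted p = 0.000543; adjusted p = 0.19 with an estimated correlation). A single library is excluded (highest adjusted p 0.00112 on leaving out 1 library, preset correlation). The list median was 0.54, and whether TAZ left after the knockdown gave this cannot be told, since no group tells what remaining TAZ does to the list. Scaling cannot be told either (0.54 with median-ratio factors, which left the fold changes of this line in place). Other differences between the lines were not tested.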

How the results depend on the processing

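Directions of named genes held: by line, 2855 results under other settings kept their call and 8 weakened, with 0 reversed. On leaving out a library 3452 kept it and 88 weakened, also with 0 reversed. These genes had been named from the same libraries because they passed, mostly with large changes or small p. The numbers therefore do not cover the other calls. Of lists by line, 324 stayed the same under other settings, 60 weakened, 91 strengthened and 1 reversed: extracellular matrix in OVCAR-8 with fry for one direction (adjusted p = 0.0233; the cause was not tested). Requiring 2-fold changes left 2652 (Detroit 562), 1667 (ES-2), 576 (HCC1954), 502 (SF268), 96 (RVH-421), 804 (SKG-II) and 2376 (OVCAR-8) genes, fewer by construction, and a spread of at least 1 between lines, a setting added after the data were seen, left 4883 genes that differ between lines. Leaving out 1 library gave 10641 to 11865 genes in Detroit 562, 9758 to 10318 in ES-2, 6465 to 7356 in HCC1954, 4076 to 6502 in SF268, 950 to 1971 in RVH-421, 5962 to 7225 in SKG-II and 10103 to 11501 in OVCAR-8; in RVH-421 it was 1102 without siNTC replicate 3 and 950 without siYAP/TAZ replicate 2, and the cause was not tested. Genes shared by all 7 lines were 118 to 166 with 2 libraries per group (166, 118 and 128 without replicate 1, 2 and 3) and 1700 in at least 6 lines. Lists called per line were 5 with an estimated correlation, 104 with fry for one direction and 124 with fry for either, which does not compare with other genes, and 67 to 70 on leaving out a library. The YAP/TAZ target list lost its call with an estimated correlation in each line (0.285 in Detroit 562, 0.19 in ES-2, 0.129 in HCC1954, 0.238 in SF268, 0.294 in RVH-421, 0.157 in SKG-II and 0.0789 in OVCAR-8), and differences between lines went from 52 to 16. NF-kB in ES-2 was at 0.0549 without siNTC replicate 3. The 6-line average ran from 9512 to 9746 and the differences from 9766 to 11122 without 1 replicate number, and from 9499 to 11193 and 10348 to 12411 without 1 of the 6 lines. No paired analysis was possible because the labels give no shared replicate numbers; the numbers used here are names in accession order. In simulated counts of independent genes 88% to 96% of 1.5-fold changes were found per line. Smaller changes and correlated genes were not simulated.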

Other observations

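Markers outside the comparisons were read as values. The squamous keratin KRT5 was at 920 CPM in Detroit 562, 529 in HCC1954 and 335 in SKG-II in the siNTC libraries. The glial markers GFAP and OLIG2 were at 0.198 and 0.0929 CPM in SF268.

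Genes that FOXO factors are known to induce, among them BMF, PIK3IP1 and BCL2L11, rose in several lines, so a list of 18 FOXO targets without them was tested on the 6-line average, chosen after the result was seen. It held 11 rises and 4 falls (median 0.29), with KLHL24 at 1.20 ± 0.036, FBXO32 at 1.12 ± 0.032 and YPEL3 at 1.10 ± 0.043 and GADD45B at -0.86 ± 0.035. FBXO32 was at 2.93 in ES-2 and 2.49 in OVCAR-8, but at -0.135 in HCC1954 and 0.076 in SKG-II. Rises outnumbered falls in every line, but only by 8 to 5 in HCC1954 (median 0.059) and in SKG-II (0.145). The members KLHL24, YPEL3, CCNG2 and CDKN1B were also called as rising in every line, so the list partly repeats that result. The camera p was 0.00159 with the preset correlation and 0.0281 with an estimated one. The latter is 0.0562 after adjusting over the 2 lists tested this way. Higher FOXO activity therefore remains possible but was not settled.

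STRA6, DHRS3 and PLAAT4, which retinoic acid is known to induce, rose on average, and a list of 13 other retinoic acid responders was tested in the same way. It held 5 rises and 2 falls (median 0.19; camera p = 0.449 with an estimated correlation), so higher retinoic acid signalling cannot be told from its absence.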
